A study of Mus musculus with 6 samples.

How the data were processed

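Gene expression was measured on 6 one-colour microarrays of mouse macrophages, 2 arrays for each of 3 groups. The sample titles name the groups naive, ID8 Day5 and ID8 Day21. They are called here naive peritoneal macrophages and tumour-associated macrophages taken 5 and 21 days into the experiment with ID8 cells. The titles themselves hold neither "peritoneal" nor "tumour-associated", and give no day for the naive group. ID8 is a mouse ovarian cancer line derived from ovarian surface epithelium. Per the labels' protocols, all cells were sorted as CD45.2+, CD19-, CD11b+, CD115+ and F4/80+, and the total RNA was end-labelled with biotin. The labels do not say that the arrays of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

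The deposited table holds log2 expression values made by the authors, 1 for each of 28853 probe sets and array. The log2 scale was read from the values, which ran from 3.07 to 14.7. The background correction, summarization and normalization behind them are not given in the sources used here. The array medians lay between 7.63 and 7.72, and at a given rank the arrays differed by 0.083 on average and by at most 0.14. The values come without a detection call, so signal over background and saturation are unknown, and the number of arrays limits the precision.

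Because the quantiles differed, the values were quantile normalized over all probe sets, as the design, written before the data were examined, asks in that case. Quantile normalization had also been listed as a variation on the values as deposited; the roles were exchanged, so the values as deposited are a variation added after seeing the data. Gene names came from the platform annotation, which gave 1 symbol for 21789 probe sets and several for 1621, and did not list 5443. Of the probe sets with 1 symbol, 21698 matched a RefSeq table (assembly GRCm38.p6) by Entrez identifier, and 0 symbols needed an update. No coordinates were used, since the build behind the deposited values is not given in the sources used here. For the 999 genes with more than 1 probe set the brightest was kept, which left 19938 genes, with no filter on dim genes. Probe sets of near-identical family members (such as Cd209, Schlafen, Mcpt and Chil genes) may bind each other's transcripts.

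The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 4.40 prior degrees of freedom). Comparisons were Day 5 against naive, Day 21 against naive and Day 21 against Day 5, each two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Changes are log2 fold changes with the standard error of the fit. Gene lists fixed in the same design, 26 in number, covered macrophage programmes, handling stress and other cell types; 25 had at least 5 measured members, and the erythroid list was not tested. They were tested with limma's camera (preset correlation 0.01, adjusted over the lists), again with a correlation estimated per list, and with fry. In camera with an estimated correlation, 0 lists passed in any comparison. The counts at an unadjusted p under 0.05 were then 3, 3 and 0 of 25 for Day 5 against naive, Day 21 against naive and Day 21 against Day 5.

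Named genes followed a rule of the same design. It took, per comparison, the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap between the groups, leaving out predicted loci, olfactory and vomeronasal receptors, small RNA genes and antigen receptor segments. It also took up to 4 changed members of each described list, or the 2 with the smallest p where fewer than 2 passed, and a fixed panel of sorting markers and macrophage genes. The panel genes Cd19 and Ly6c2 had no probe set with a single name and were not analysed here. Genes outside the rule are marked as chosen after their values were seen.

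The tests were tried on simulated arrays of 19938 genes, with 200 genes changed and a gene list shifted by 0.3. Means were the measured ones, and noise was drawn independently per gene from the spreads that eBayes had moderated toward the prior. Simulated genes thus spread less widely than some measured ones and did not vary together. The shares found may therefore be higher than in the data. For Day 5 against naive, 75.9% of changes of 0.5, 99.9% of changes of 1 and 100% of changes of 2 were found. The shares at a change of 0.5 were 75.7% for Day 21 against naive and 78.1% for Day 21 against Day 5. Of all simulated calls, 7.66%, 7.99% and 7.75% were false in Day 5 against naive, Day 21 against naive and Day 21 against Day 5, above the nominal rate.

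Alternatives of the design were median centring, dropping the genes dimmer than the median gene, a variance prior with trend and robust settings, only the 4 arrays compared, other rules for several probe sets of a gene, a fold threshold, the replicate number as a block, other list tests, and leaving out each array. Added after seeing the data were the values as deposited, quantile normalization over named probe sets only, and a crossed replicate block. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.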

Results

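The series followed gene expression in macrophages over the growth of ID8 tumours, from naive peritoneal macrophages to tumour-associated macrophages (TAMs) at Day 5 and Day 21, with 2 arrays per group. The sorted cells kept the transcripts of their sorting markers. Ptprc (CD45), Itgam (CD11b), Csf1r (CD115) and Adgre1 (F4/80) differed by at most 0.10 on the log2 scale in any comparison (Ptprc, Day 21 against naive), and none passed the test. Gata6, the transcription factor of resident peritoneal macrophages, had log2 means of 12.92 ± 0.00049 (SD) in naive, 12.88 ± 0.10 in Day 5 and 12.88 ± 0.07 in Day 21 macrophages. The receptor gene Timd4, also of resident cells, differed from naive by -0.15 ± 0.09 (SE) at both times. Its naive arrays lay at 13.32 (replicate 1) and 13.13 (replicate 2), and its means at 13.07 (Day 5) and 13.08 (Day 21). The resident macrophage list (20 genes) had mean changes of -0.023 at Day 5 and 0.045 at Day 21 against naive, neither past the test. Its mean per array, centred on the groups, was 0.032 and -0.047 in naive and -0.0013 and -0.059 in Day 5 arrays, which overlapped. In Day 21 arrays it was 0.036 and 0.040. Arrays correlated across genes at 0.997 within each group and at 0.994 to 0.997 between groups. The first principal component held 38.6% of the variance and set the Day 5 arrays (-17.2 and -15.5) apart from the other 4 (5.87 to 10.4).

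In Day 5 TAMs against naive macrophages, members of the mast cell and monocyte lists rose. Cpa3, the mast cell carboxypeptidase, rose 5.75-fold (log2 change 2.52 ± 0.21, SE). Tdo2, which starts the breakdown of tryptophan, rose 3.33-fold (1.73 ± 0.12). The chitinase-like gene Chil3 rose 2.83-fold (SE 0.17 on the log2 scale) and the C-type lectin gene Cd209d rose 2.80-fold (1.49 ± 0.20). Siglec1, a sialic acid-binding receptor of macrophages, fell 2.69-fold (-1.43 ± 0.19), and the interferon-induced gene Ifi27l2a fell 2.01-fold (-1.01 ± 0.08).

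In all, 53 of 19938 genes passed the threshold in limma (46 higher and 7 lower), and 16 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3113 genes, against 996.9 by chance. The other large rises were Gdpd1 (1.62 ± 0.21), the NF-kappaB inhibitor gene Tnip3 (1.39 ± 0.10), the mast cell chymase gene Mcpt4 (1.30 ± 0.11), the receptor gene Slamf7 (1.29 ± 0.11), the B cell receptor chain gene Cd79b (1.27 ± 0.17) and Gpr132 (1.19 ± 0.14). Falls were also seen in Slfn4 (-0.86 ± 0.08), the respiratory complex subunit gene Uqcr11 (-0.67 ± 0.09), Rbm8a (-0.62 ± 0.08) and Dtd1 (-0.58 ± 0.08). Without naive replicate 1 or naive replicate 2, 0 genes passed in limma, with 2773 and 2850 at an unadjusted p under 0.05, and the count was 15 without Day 5 replicate 1 and 30 without either Day 21 array. The share of higher genes was 86.8%, against 97.2% with median centring and 95.5% with the values as deposited.

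Of the monocyte and monocyte-derived macrophage list (19 genes) at Day 5, 3 members rose over all genes and 7 adjusted over the list alone, with a mean change of 0.47. Its camera test gave an adjusted p of 1.58e-07, and adjusted p = 0.246 with an estimated correlation. Those that rose were Chil3, the receptor gene Treml4 (1.12 ± 0.08) and the fractalkine receptor gene Cx3cr1 (0.83 ± 0.09). The chemokine receptor gene Ccr2 had a change of 1.80 ± 0.31 (adjusted p = 0.0739). The MHC class II list (13 genes) had a mean of 0.34 (camera adjusted p = 1.67e-05, adjusted p = 0.290 with an estimated correlation). None of its members passed over all genes, and 8 were higher and 1 lower adjusted over the list alone. Among them, H2-Aa differed by 0.77 ± 0.13 and the transactivator gene Ciita by 1.11 ± 0.18. In the interleukin-4 and STAT6 list (28 genes, mean 0.25) Chil3 and Tfec (0.84 ± 0.11) rose, and 4 were higher adjusted over the list alone. For the interleukin-4 and STAT6 list the camera adjusted p was 0.00140, and adjusted p = 0.246 with an estimated correlation. The NF-kappaB list (23 genes, mean 0.31) had 0 members past the test over all genes and 6 higher adjusted over the list alone. The NF-kappaB list had a camera adjusted p of 2.65e-04, and adjusted p = 0.290 with an estimated correlation. Il6 had a change of 1.67 ± 0.31 and Tnfaip2 of 0.46 ± 0.08.

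Lower as a list at Day 5 were cell cycle, type I interferon and oxidative phosphorylation genes. All 29 cell cycle genes had negative changes under each of the 3 scalings (mean -0.49). Of them 0 passed the test over all genes and 2 were lower adjusted over the list alone, Pcna (-0.51 ± 0.09) and Aurka (-0.49 ± 0.10). The estimated correlation among these genes was 0.84, so their shared sign does not amount to 29 separate observations. The list's mean per array, centred on the groups, was 0.061 and 0.45 in naive and -0.45 and -0.014 in Day 5 arrays. For the cell cycle list the camera adjusted p was 3.31e-11, and adjusted p = 0.396 with an estimated correlation, and its mean was -0.27 without Day 5 replicate 1 and -0.29 without naive replicate 2. All 23 type I interferon targets had negative changes, again under each scaling (mean -0.34), 0 over all genes and 12 adjusted over the list alone passing. The estimated correlation among them was 0.36, so they are not 23 separate observations either. The type I interferon list had a camera adjusted p of 8.44e-09, and adjusted p = 0.293 with an estimated correlation, and its mean was -0.20 without naive replicate 1. Examples were Oas3 (-0.83 ± 0.13) and Oasl2 (-0.36 ± 0.08). Of 27 oxidative phosphorylation genes (mean -0.14), 0 passed over all genes and 4 were lower adjusted over the list alone, among them Ndufa4 (-0.48 ± 0.08) and Cycs (-0.36 ± 0.08). For the oxidative phosphorylation list the camera adjusted p was 1.77e-05, and adjusted p = 0.290 with an estimated correlation.

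Markers of cell types other than macrophages moved beside these groups at Day 5. The mast cell list (9 genes) had a mean of 0.57 and a median of 0.090, with Cpa3 and Mcpt4 past the test over all genes and 4 higher adjusted over the list alone. The mast cell list had a camera adjusted p of 4.75e-05, and adjusted p = 0.290 with an estimated correlation. All 12 dendritic cell genes had positive changes, or 11 with median centring or the values as deposited (mean 0.31), 0 over all genes and 5 adjusted over the list alone passing, among them Kmo (0.58 ± 0.10) and Ccr7 (0.35 ± 0.09). For the dendritic cell list the camera adjusted p was 1.77e-05, and adjusted p = 0.246 with an estimated correlation. In the B cell list (13 genes, mean 0.22, median 0.015) Cd79b and Cd79a (0.68 ± 0.08) rose and 3 were higher adjusted over the list alone, although CD19+ cells had been gated out. The B cell list had a camera adjusted p of 0.0192, and adjusted p = 0.341 with an estimated correlation, and the call was lost without Day 5 replicate 1 (mean 0.17) or naive replicate 1 (mean 0.17). The other 15 lists did not pass, with means from -0.091 for cholesterol biosynthesis to 0.14 for matrix remodelling and growth factors. In this range lay the T and NK cell (0.060), neutrophil (0.039), eosinophil (0.050), ovarian epithelial and mesothelial (0.13), fibroblast and endothelium (0.070), immune checkpoint (0.085), lysosome and lipid-handling (0.082), glycolysis and hypoxia (0.0078), cholesterol efflux (0.074) and immediate early and stress (0.045) lists. Mean, median and test differed in sign for interferon-gamma targets (mean 0.0041), complement and scavenging (0.028), eosinophils, and fibroblasts and endothelium. Single members of these lists past the test were Nr1h3, the sterol receptor LXR alpha (0.72 ± 0.09), in the cholesterol efflux list, the scavenger receptor gene Marco (0.86 ± 0.10) in the complement and scavenging list, and Siglec1 in the immune checkpoint list.

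**Figure D1:**
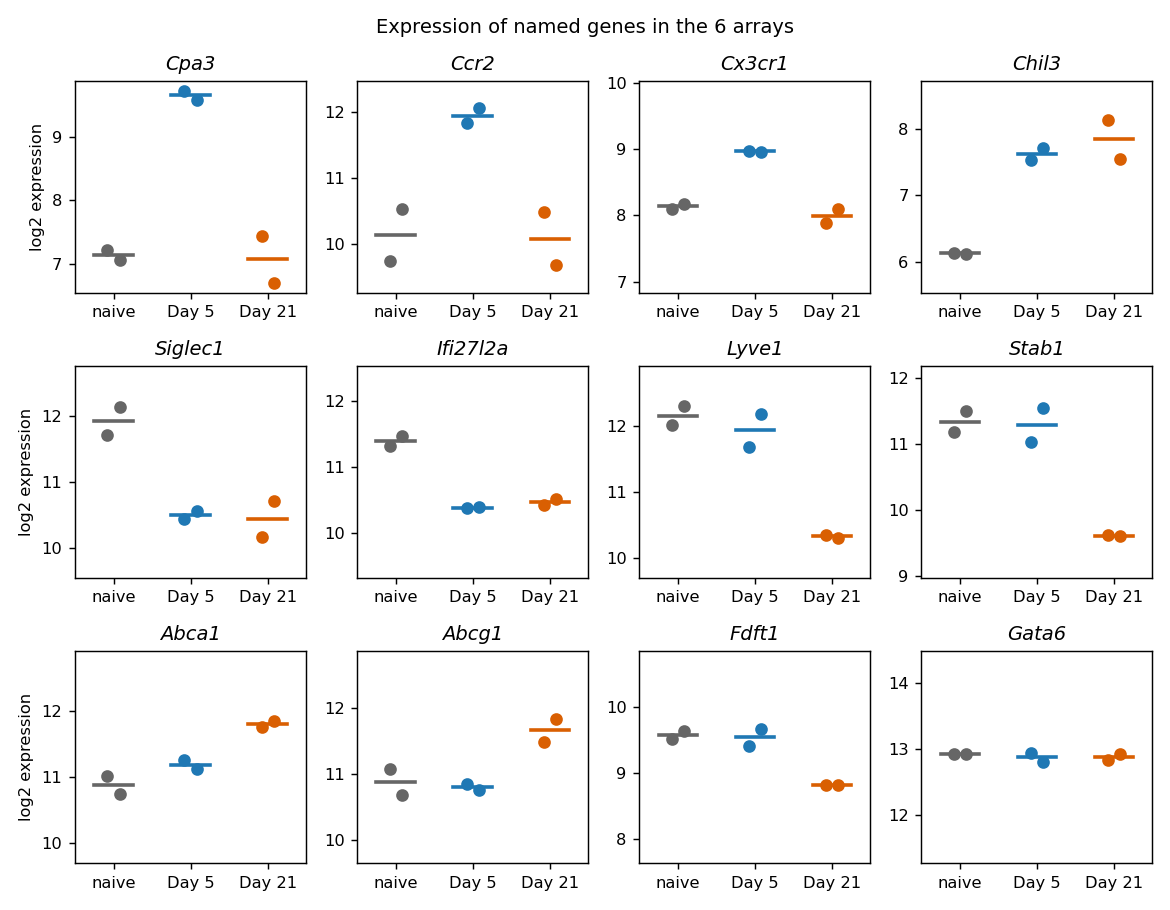
Log2 expression of 12 genes (vertical axis) in naive, Day 5 and Day 21 macrophages, with 1 point per array and a line at the mean of 2 arrays. Cpa3 and Cx3cr1 were highest at Day 5, Lyve1 and Stab1 lowest at Day 21, and Gata6 lay between 12.88 and 12.92 in all 3 group means.

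In Day 21 TAMs against naive macrophages, the endocytic receptor genes Lyve1 and Stab1 fell, and Chil3 and the clock gene Per2 rose. Lyve1, a hyaluronan receptor, fell 3.55-fold (-1.83 ± 0.17) and Stab1, a scavenger receptor, fell 3.31-fold (-1.72 ± 0.17). Nr1d1, the clock repressor REV-ERB alpha, fell 2.18-fold (-1.13 ± 0.10), and Ifi27l2a fell 1.89-fold (-0.92 ± 0.08). Chil3 rose 3.30-fold (1.72 ± 0.17), and Per2 (1.17 ± 0.12), the tyrosine catabolism gene Hgd (1.17 ± 0.11) and Dgkh (0.68 ± 0.07) rose. These 8 genes, 4 higher and 4 lower, were all that passed in limma, and 1683 genes had an unadjusted p under 0.05, against 996.9 by chance. Without naive replicate 1 or naive replicate 2, 0 genes passed in limma, with 1776 and 1720 at an unadjusted p under 0.05, and without Day 21 replicate 1 or Day 21 replicate 2 the counts were 1 and 4.

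Cholesterol biosynthesis genes were lower as a list at Day 21 (20 genes, mean -0.37), with 0 past the test over all genes and 13 lower adjusted over the list alone. For the cholesterol biosynthesis list the camera adjusted p was 5.99e-14, and adjusted p = 0.317 with an estimated correlation. Fdft1, which encodes squalene synthase, had a change of -0.76 ± 0.10 and Srebf2, the transcription factor of this pathway, of -0.55 ± 0.08. The cholesterol efflux and LXR target list (18 genes) had a mean of 0.20 and a median of 0.027, with 0 past the test over all genes and 3 higher adjusted over the list alone. The cholesterol efflux list had a camera adjusted p of 0.0272, and adjusted p = 0.412 with an estimated correlation, and the call was lost without naive replicate 2 (mean 0.14) or Day 21 replicate 2 (mean 0.14), with the dimmer genes dropped (mean 0.21), and with trend and robust variance settings. The efflux transporter genes Abca1 and Abcg1 had changes of 0.92 ± 0.11 (adjusted p = 0.0747) and 0.78 ± 0.16 (adjusted p = 0.261). The complement and scavenging list (22 genes, mean -0.24, median -0.067) held the falls of Lyve1 and Stab1, with 1 higher and 2 lower adjusted over the list alone. For the complement and scavenging list the camera adjusted p was 0.00876, and adjusted p = 0.317 with an estimated correlation, and the call was lost without naive replicate 2 (mean -0.18).

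All 23 type I interferon targets, whose estimated correlation was 0.36, had negative changes at Day 21 against naive, under each scaling (mean -0.37). Of them 0 passed the test over all genes and 9 were lower adjusted over the list alone, among them Oas1a (-0.55 ± 0.09) and Oasl1 (-0.64 ± 0.11). The same 2 naive arrays served at Day 5, so this is not a separate observation from the fall of the list there. The type I interferon list had a camera adjusted p of 9.51e-12, and adjusted p = 0.317 with an estimated correlation, and its mean was -0.22 without naive replicate 1. The cell cycle list (mean -0.28, 0 past either test) had a camera adjusted p of 2.83e-06, and adjusted p = 0.611 with an estimated correlation. Its call was lost without naive replicate 2 (mean -0.082) or Day 21 replicate 1 (mean -0.13), and the mean was -0.47 without naive replicate 1 and -0.42 without Day 21 replicate 2. Aurka and Cdc20 had changes of -0.30 ± 0.10 and -0.31 ± 0.11, the latter -0.16 without naive replicate 2. The NF-kappaB list (mean 0.28) had 0 past the test over all genes and 5 higher adjusted over the list alone, among them Tnfaip2 (0.70 ± 0.08) and Icam1 (0.66 ± 0.12). For the NF-kappaB list the camera adjusted p was 2.06e-05, and adjusted p = 0.317 with an estimated correlation. The MHC class II list (mean 0.18) had 0 and 4 past these tests, among them H2-Aa (0.53 ± 0.13) and Cd74 (0.49 ± 0.13). Both sizes depend on the naive array, since naive replicates 1 and 2 lay at 12.39 and 12.75 for H2-Aa and 12.80 and 13.17 for Cd74. The MHC class II list had a camera adjusted p of 7.18e-04, and adjusted p = 0.336 with an estimated correlation, and the call was lost without Day 21 replicate 2 (mean 0.13). In the monocyte list (mean 0.11) Chil3 rose, and 4 were higher and 2 lower adjusted over the list alone. For the monocyte list the camera adjusted p was 0.0157, and adjusted p = 0.402 with an estimated correlation, and the call was lost without naive replicate 1 (mean 0.044) or Day 21 replicate 1 (mean 0.019), while the mean was 0.17 without naive replicate 2 and 0.20 without Day 21 replicate 2.

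The immediate early and stress list (19 genes), which marks handling of cells, had a mean of 0.24 at Day 21 beside these groups, with 0 past the test over all genes and 2 higher adjusted over the list alone, Fos (0.71 ± 0.15) and Fosb (0.35 ± 0.08). The immediate early list had a camera adjusted p of 1.38e-06, and adjusted p = 0.317 with an estimated correlation. Ovarian epithelial and mesothelial genes (16 genes) had a mean of 0.11, with 0 past either test, and Krt19 and Wt1 had changes of 0.60 ± 0.16 and 0.24 ± 0.08. For the ovarian and mesothelial list the camera adjusted p was 0.00876, and adjusted p = 0.317 with an estimated correlation, and the call was lost without naive replicate 1 (mean 0.076). The other 15 lists did not pass, with means from -0.13 for lysosome and lipid-handling genes to 0.096 for interferon-gamma targets. Among them were mast cells (0.0073), dendritic cells (-0.022), B cells (0.034), T and NK cells (-0.026), neutrophils (-0.029), eosinophils (-0.091), fibroblasts and endothelium (0.057), glycolysis and hypoxia (0.065) and oxidative phosphorylation (-0.038). Mean, median and test differed in sign for 6 of these lists, the interleukin-4 and STAT6 (0.067, in which Chil3 rose), matrix remodelling (-0.025), immune checkpoint (-0.048), T and NK cell, mast cell and dendritic cell lists.

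**Figure D2:**
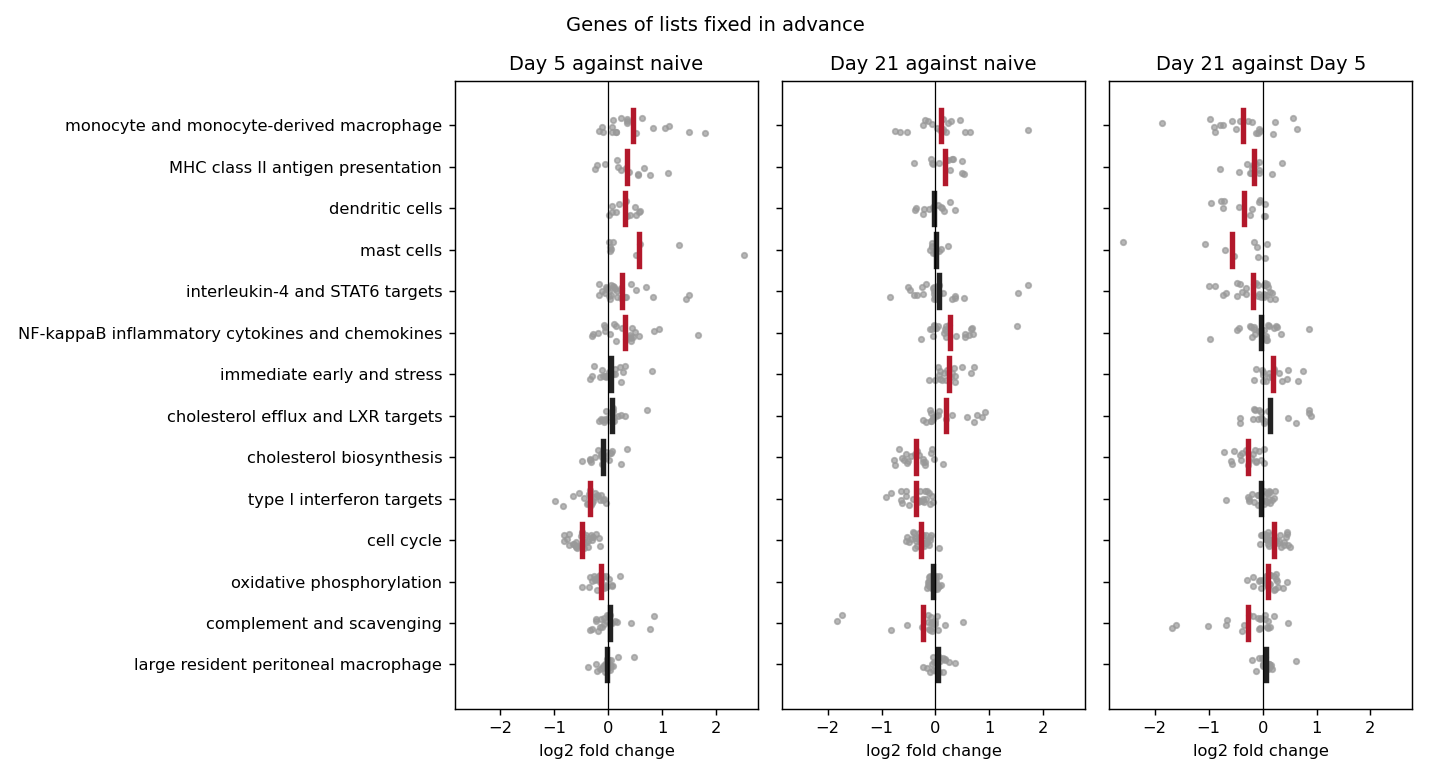
Log2 fold change (horizontal axis) of each gene of 14 lists fixed in advance, in 3 comparisons, with 1 grey point per gene and a bar at the list's mean, red where the list passed camera with a preset correlation. The means of the cholesterol biosynthesis list were -0.091 at Day 5 and -0.37 at Day 21 against naive, and no list passed with an estimated correlation.

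Between Day 5 and Day 21, most of the genes that changed were lower at Day 21. Cpa3 fell 6.02-fold (-2.59 ± 0.21), Nr1d1 fell 4.30-fold (-2.10 ± 0.10) and Ccr2 fell 3.63-fold (-1.86 ± 0.31). Stab1 (-1.68 ± 0.17), Lyve1 (-1.61 ± 0.17), Slamf7 (-1.68 ± 0.11), Tnip3 (-1.62 ± 0.10) and Tdo2 (-1.37 ± 0.12) also fell. The clock repressor genes Cry1 and Per2 rose 2.64-fold (1.40 ± 0.16) and 2.35-fold (1.23 ± 0.12).

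The threshold was passed by 166 genes in limma, 34 higher and 132 lower at Day 21, and 35 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3320 genes, against 996.9 by chance. Further rises were in the heat shock gene Hsph1 (0.91 ± 0.12), Cisd1 (0.91 ± 0.12), the interferon-gamma-induced gene Iigp1 (0.90 ± 0.13), the niacin receptor gene Hcar2 (0.85 ± 0.14), Uqcr11 (0.83 ± 0.09), Setbp1 (0.83 ± 0.13), Hgd (0.72 ± 0.11) and Kcnn3 (0.69 ± 0.07). Rcn3 (-1.52 ± 0.21) and Dnah12 (-1.42 ± 0.18) fell, but a second, dimmer probe set of Dnah12 gave -0.052. Without 1 array of either TAM group the count was 21 (Day 5 replicate 1), 17 (Day 5 replicate 2), 18 (Day 21 replicate 1) or 5 (Day 21 replicate 2). The share of higher genes was 20.5%, against 6.75% with median centring and 8.25% with the values as deposited.

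Of the mast cell list, Cpa3, Mcpt4 (-1.06 ± 0.11) and Tpsb2 (-0.69 ± 0.11) fell from Day 5 to Day 21 (mean -0.56), and 4 were lower adjusted over the list alone. The mast cell list had a camera adjusted p of 4.78e-04, and adjusted p = 0.353 with an estimated correlation. In the monocyte list (mean -0.36) Ccr2, Cx3cr1 (-0.98 ± 0.09), Itgax (-0.88 ± 0.12) and Ms4a4c (-0.79 ± 0.13) fell and 2 members rose, with 2 higher and 9 lower adjusted over the list alone. Those that rose, Plac8 (0.64 ± 0.09) and Fcgr4 (0.56 ± 0.09), were chosen after their values were seen. For the monocyte list the camera adjusted p was 0.00156, and adjusted p = 0.353 with an estimated correlation. Of the dendritic cell genes (mean -0.34), Kmo (-0.95 ± 0.10) and Clec9a (-0.78 ± 0.12) fell and 4 were lower adjusted over the list alone. The dendritic cell list had a camera adjusted p of 0.00156, and adjusted p = 0.353 with an estimated correlation. With the dimmer genes dropped, the monocyte and dendritic cell calls were lost (means -0.30 and -0.29).

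Of the cholesterol biosynthesis genes (mean -0.28), Fdft1 fell (-0.72 ± 0.10), 10 were lower adjusted over the list alone, and Cyp51 had a change of -0.59 ± 0.10. For the cholesterol biosynthesis list the camera adjusted p was 1.56e-06, and adjusted p = 0.353 with an estimated correlation. Abca1 and Abcg1 had changes of 0.62 ± 0.11 (adjusted p = 0.0551) and 0.86 ± 0.16 (adjusted p = 0.0604), and their list did not pass (mean 0.13, median -0.024). The complement and scavenging list (mean -0.27) held the falls of Stab1 and Lyve1, with 4 lower adjusted over the list alone. The complement and scavenging list had a camera adjusted p of 0.0350, and adjusted p = 0.353 with an estimated correlation, and its call was lost without Day 5 replicate 2 (mean -0.25), without Day 21 replicate 1 (mean -0.28) and with the dimmer genes dropped (mean -0.27).

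The immediate early and stress list had a mean of 0.20 beside these groups, with 0 past the test over all genes and 4 higher adjusted over the list alone, among them Fosb (0.45 ± 0.08) and Fos (0.75 ± 0.15). For the immediate early list the camera adjusted p was 9.23e-04, and adjusted p = 0.353 with an estimated correlation, and its mean was 0.13 without Day 5 replicate 2. Oxidative phosphorylation genes had a mean of 0.10 (0.065 with median centring and 0.068 with the values as deposited), with 0 past the test over all genes and 4 higher and 1 lower adjusted over the list alone, among them Cycs (0.46 ± 0.08) and Ndufa4 (0.37 ± 0.08). The oxidative phosphorylation list had a camera adjusted p of 0.00156, and adjusted p = 0.422 with an estimated correlation. The cell cycle list (mean 0.21, 0 past either test) had a camera adjusted p of 0.00175, and adjusted p = 0.637 with an estimated correlation. Its mean was -0.0069 without Day 5 replicate 1, 0.43 without Day 5 replicate 2, 0.36 without Day 21 replicate 1 and 0.066 without Day 21 replicate 2, and the call was lost in the first and the last of these. Pcna and Mcm4 had changes of 0.31 ± 0.09 and 0.46 ± 0.17.

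The remaining lists past the camera test were lower at Day 21 than at Day 5, each with 0 members past the test over all genes. The interleukin-4 and STAT6 list had a mean of -0.18 and 4 members lower adjusted over the list alone, with Retnla at -0.68 ± 0.12 and Egr2 at -0.88 ± 0.15. For the interleukin-4 and STAT6 list the camera adjusted p was 0.0150, and adjusted p = 0.353 with an estimated correlation, and its call was lost without Day 5 replicate 2 (mean -0.16) or Day 21 replicate 2 (mean -0.15). The lysosome and lipid-handling list (23 genes, mean -0.21) had 2 members lower adjusted over the list alone, Gpnmb (-0.78 ± 0.18) and Lgals1 (-0.81 ± 0.19). The lysosome list had a camera adjusted p of 0.0197, and adjusted p = 0.429 with an estimated correlation, and its call was lost without Day 21 replicate 2 (mean -0.18) and with the dimmer genes dropped (mean -0.23). The MHC class II list (mean -0.16) had 3 members lower adjusted over the list alone, with Ciita at -0.79 ± 0.18 and Ifi30 at -0.29 ± 0.07. In Ciita, Day 5 replicates 1 and 2 lay apart, at 9.13 and 9.69, beside a Day 21 mean of 8.62. For the MHC class II list the camera adjusted p was 0.0396, and adjusted p = 0.429 with an estimated correlation, and its call was lost without Day 5 replicate 2 (mean -0.11), without Day 21 replicate 1 (mean -0.11), with the dimmer genes dropped (mean -0.17) and with the values as deposited (mean -0.18). The other 14 lists did not pass, with means from -0.18 for B cells, in which Cd79b fell (-1.20 ± 0.17), to 0.13 for cholesterol efflux. Among them were resident macrophages (0.068), interferon-gamma targets (0.092, in which Iigp1 rose), glycolysis and hypoxia (0.057), matrix remodelling (-0.17), immune checkpoint (-0.13) and neutrophil (-0.068) genes. Mean, median and test differed in sign for 7 of them, the cholesterol efflux, type I interferon (-0.024), NF-kappaB (-0.029), ovarian epithelial and mesothelial (-0.020), T and NK cell (-0.087), eosinophil (-0.14), and fibroblast and endothelium (-0.014) lists.

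**Figure D3:**
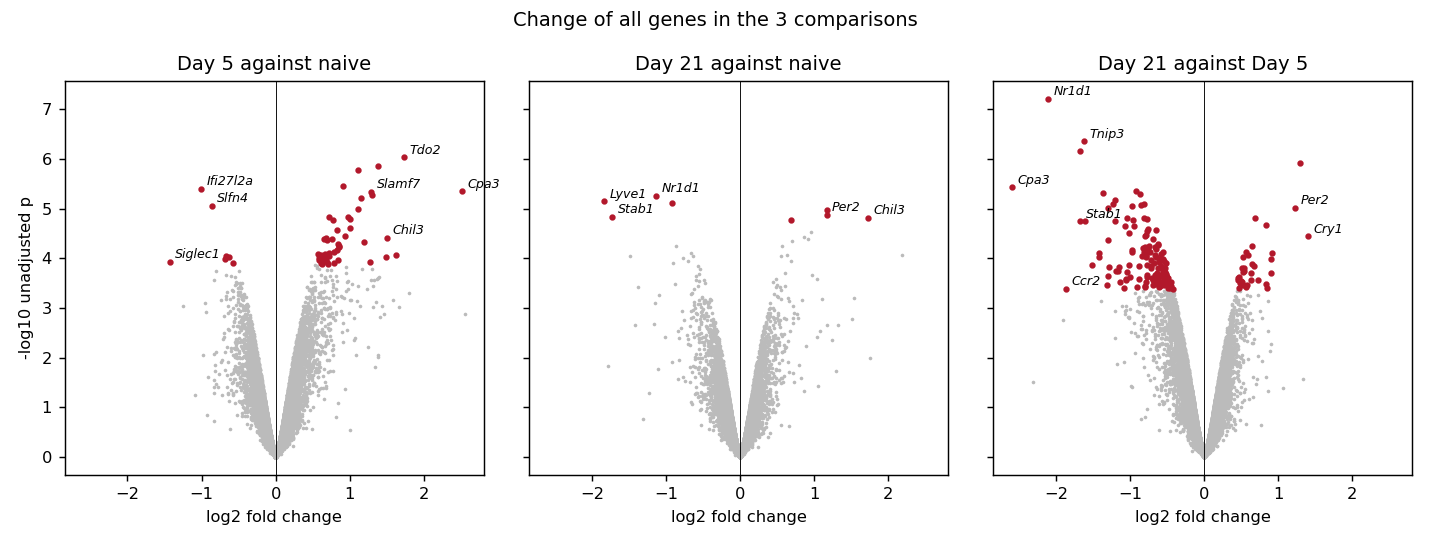
Log2 fold change (horizontal axis) against the negative log10 of the unadjusted p from limma (vertical axis) for 19938 genes in 3 comparisons, with 1 point per gene and genes past the adjusted threshold in red. The red points number 53 at Day 5 and 8 at Day 21 against naive, and 166 between Day 5 and Day 21.

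Few genes passed the threshold at both times against naive. Only 8 genes passed at Day 21 against naive, so no more than 8 could be shared. A small overlap therefore does not show that the 2 times differ in their changes. Chil3 was higher and Ifi27l2a lower in both comparisons, and Nr1d1 was higher at Day 5 (0.98 ± 0.10) and lower at Day 21. Independent sets of these sizes would share 0.0092 higher and 0.0014 lower genes. Simulated unchanged groups, set against the same simulated naive arrays, shared 0.040 genes on average and at most 2 in 100 simulations. Unchanged groups give few calls, so this number does not show how far shared arrays raise the overlap of called genes. The changes correlated across genes, which are not independent replicates, at 0.389, against 0.50 in the simulations, with a covariance of 0.0110 against 0.00526 simulated and a difference of 0.00576. The 2 naive arrays could not be split into parts of 2, so part of the excess over independent sets may come from the shared controls. The simulated correlation and covariance include the effect of shared controls on unchanged genes. Of the 53 genes changed at Day 5, 30 passed in the opposite direction between Day 5 and Day 21 (26 higher then lower, 4 lower then higher). Independent sets would share 0.305 and 0.012 such genes. Simulated unchanged groups shared 0.030 on average and at most 1, but they too give few calls. That number does not show what the Day 5 arrays, used in both comparisons, add, so part of the 30 may come from them. Of the 166 genes that differed between Day 5 and Day 21, 131 passed in neither comparison with naive.

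Of the fixed macrophage panel, Apoe, Nos2 and Il12b differed by at most 0.067 in any comparison (Il12b, Day 21 against Day 5). Group means of Apoe were 14.31 to 14.35, close to the array maxima of 14.65 to 14.70. Those of Nos2 (6.98 to 7.03) and Il12b (6.52 to 6.58) lay below the array median of 7.67. At such levels a change may go unseen, so these values do not show that expression was unchanged. Leaving out naive replicate 1 brought Il12b to -0.14 at Day 5, and leaving out naive replicate 2 brought it to 0.10 at Day 21 against naive. Between Day 5 and Day 21 it was 0.13 without Day 21 replicate 1 and 0.10 without Day 5 replicate 2. None of the following passed the test, and the ranges are those with 1 array left out at a time. Arg1 had changes against naive of 0.08 ± 0.18 at Day 5 and -0.39 ± 0.18 at Day 21, the latter from -0.70 without Day 21 replicate 2 to -0.08 without Day 21 replicate 1. The size at Day 5 depends on the naive array, with naive replicates 1 and 2 at 11.36 and 11.45 and a Day 5 mean of 11.48. Mrc1 had changes of 0.42 ± 0.19 and 0.04 ± 0.19, from 0.16 and -0.22 without naive replicate 1 to 0.69 and 0.31 without naive replicate 2. Il10 had changes of 1.34 ± 0.43 at Day 5, from 0.58 without Day 5 replicate 1 to 2.09 without Day 5 replicate 2, and 0.56 ± 0.43 at Day 21, or 0.29 without Day 21 replicate 2. Cxcl9 had changes of 0.49 ± 0.42 at Day 5 and 1.05 ± 0.42 at Day 21, the latter from 0.26 without Day 21 replicate 2 to 1.85 without Day 21 replicate 1. Mki67 had changes of -0.45 ± 0.26 at Day 5, from -0.80 without Day 5 replicate 2 to -0.10 without Day 5 replicate 1, and -0.10 ± 0.26 at Day 21, from -0.43 without naive replicate 1 to 0.23 without naive replicate 2. Retnla had changes of 0.33 ± 0.12, or 0.19 without Day 5 replicate 2, and -0.35 ± 0.12.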

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

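The tests of explanations given here were all chosen after the results were seen, while the tests of the differences themselves were planned. A first criterion for fewer cycling cells, as the cause of lower cholesterol synthesis genes, had excluded it and was replaced, once that outcome was known, by one that asks for arrays that do not overlap. The change against naive differed between Day 5 and Day 21 for the genes and lists that follow, by the limma or camera test of Day 21 against Day 5, in which the naive arrays cancel.

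Lower at Day 21 than at Day 5 were Cpa3 (difference -2.59 on the log2 scale), Nr1d1 (-2.10), Slamf7 (-1.68), Stab1 (-1.68), Tnip3 (-1.62), Lyve1 (-1.61), Tdo2 (-1.37), Cd209d (-1.30), Cd79b (-1.20), Mcpt4 (-1.06) and Cx3cr1 (-0.98). Higher at Day 21 were Per2 (1.23), Uqcr11 (0.83), Hgd (0.72), Dtd1 (0.54), Dgkh (0.53) and Rbm8a (0.52). Among lists, the mean difference was -0.56 for mast cells, -0.36 for monocytes and monocyte-derived macrophages, -0.34 for dendritic cells, -0.28 for cholesterol biosynthesis, -0.27 for complement and scavenging, -0.18 for interleukin-4 and STAT6 targets and -0.16 for MHC class II. It was 0.21 for the cell cycle, 0.20 for immediate early and stress genes and 0.10 for oxidative phosphorylation. No list passed with an estimated correlation. Among the 7064 probe sets without a single gene name, which entered no comparison, 15 passed for Day 21 against Day 5 when fitted and adjusted with all probe sets, 12 higher and 3 lower. Fitted and adjusted alone, 0 passed in limma, with 947 at an unadjusted p under 0.05.

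Clock genes differed between Day 5 and Day 21, with Nr1d1 lower and Per2 and Cry1 higher at Day 21. The Nr1d1 difference was at least -2.15 in size under median centring and with the values as deposited. The deposited arrays differed by at most 0.14 at a given rank, too little for these scalings to remove such a difference. The outcome was thus fixed beforehand, and scaling done before deposition was not tested. Of the clock list, drawn up after Nr1d1, Per2 and Cry1 were seen, the 14 genes other than these had a mean absolute change of 0.29 (percentile 99.2 of 10000 random lists matched on expression), and the 13 without Nr1d2 too, which also passed, one of 0.22 (percentile 89.6). Collection at different times of day may contribute, but these values do not decide it. The labels give no collection time, so it cannot be told apart from the day of the experiment. Nr1d1 also passed against naive at Day 5 (0.98) and at Day 21 (-1.13), and Per2 at Day 21 (1.17). The same limit therefore holds for both comparisons with naive. A biological change over the course of the tumour stays open and was not tested.

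At Day 5 against naive the mast cell, monocyte and dendritic cell lists passed camera with 2 of 9, 3 of 19 and 0 of 12 members past the gene test, and adjusted p = 0.290, 0.246 and 0.246 with an estimated correlation. A larger share of monocyte-derived cells in the sort may contribute, and should lower the resident macrophage list. That list's mean was -0.023 with a standard error over members of 0.038. This error takes genes as replicates and does not measure the spread between arrays, so it does not decide the question. The list's means in naive and Day 5 arrays overlapped. Ccr2 lay at 10.14 in naive and 11.94 in Day 5 arrays. Mast cells in the sort are a candidate source, although CD115 gating should remove them; Cpa3 lay at 7.13 in naive and 9.66 in Day 5 arrays. The 4 proteases had a mean of 1.23 and the other 5 mast cell genes, Kit, Fcer1a, Ms4a2, Gata2 and Hdc, of 0.045. Only 1 of these 5 lay between the array median and a level of 10, which leaves the test void by this criterion. The proteases, however, rose from naive levels below the array median of 7.67. At levels like that of Cpa3, Kit (7.01 in naive arrays) and Gata2 (7.77) had changes of 0.090 ± 0.084 and 0.034 ± 0.12. So few genes of a like level do not decide it. A response of the macrophages themselves at Day 5 was not tested.

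The cholesterol synthesis list passed camera at Day 21 against naive and against Day 5 with 0 and 1 of 20 members past the gene test, and adjusted p = 0.317 and 0.353 with an estimated correlation. The list's mean at Day 21 against naive was -0.39 or further from 0 under median centring and with the values as deposited. With arrays at most 0.14 apart at a given rank, these scalings could move it little. They therefore do not test array scaling as a cause, and scaling done before deposition was not tested. Fewer cycling cells could lower the list, as the cell cycle mean of -0.28 beside -0.37 for synthesis at Day 21 against naive would have it, while the means of -0.49 and -0.091 at Day 5 go against it. It stays open under the later criterion, since the cell cycle mean of 0.21 from Day 5 to Day 21 was -0.0069 without Day 5 replicate 1 and 0.066 without Day 21 replicate 2, and the arrays overlapped; with that score as a covariate the synthesis score differed by -0.34 ± 0.095 (SE, 2 residual degrees of freedom) between Day 21 and naive. Sterol loading of the cells is a further hypothesis. At Day 21 against naive the efflux and LXR target list had a mean of 0.20 and a median of 0.027, with 10 members higher and 8 lower. It passed camera (adjusted p = 0.0272) but not with an estimated correlation (adjusted p = 0.412), and 3 members were higher adjusted over the list alone. These values leave the hypothesis undecided.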

How the results depend on the processing

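Apart from the values as deposited, the quantile normalization over named probe sets and the crossed block, the alternatives were planned. The counts of changed genes are given in the order Day 5 against naive (53), Day 21 against naive (8) and Day 21 against Day 5 (166), and only the values that moved by more than 1.5 times are listed. Median centring gave 108 at Day 5. Dropping the dimmer genes gave 34, 5 and 350, and 6 lists for Day 21 against Day 5. A variance prior with trend and robust settings gave 382, 23 and 622. Only the 4 arrays compared gave 30 at Day 5. A fold threshold gave 16 at Day 5 and 35 for Day 21 against Day 5. Every probe set as its own feature gave 23 at Day 5 and 0 at Day 21 against naive (1802 at an unadjusted p under 0.05 in limma). Camera with an estimated correlation gave 0 lists in each comparison, and fry gave 0 lists for Day 21 against naive (5 of 25 unadjusted) and Day 21 against Day 5 (9 of 25 unadjusted). At Day 5 against naive fry gave 7 lists, 6 of them among the 10, gaining matrix remodelling (adjusted p = 0.0453) and losing the cell cycle (0.266), type I interferon, NF-kappaB and B cell lists (0.141 each). The overlap of 2 genes became 1 with the dimmer genes dropped, 7 with trend and robust settings, 0 with only the 4 arrays compared, 1 with the fold threshold and 0 with every probe set. A fold threshold can only lower the counts, by construction. Dropping the dimmer genes moved them in both directions. Why the settings other than the fold threshold moved the counts was not tested.

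Leaving out 1 array at a time, with the lone array of a group assumed to vary like the others, gave 0 to 36, 0 to 7 and 5 to 161 genes, 10 to 12, 8 to 11 and 9 to 11 lists, and an overlap of 0 to 1. The cell cycle list for Day 21 against Day 5 ran from -0.0069, a reversal, without Day 5 replicate 1 to 0.43 without Day 5 replicate 2; the cause was not tested. For 30 of the 31 list calls the p with an estimated correlation was the highest of the alternatives; the exception was this list. Of the values of named genes, 0 of 59 called and 75 of 171 not called moved by more than 1.5 times or changed sign without 1 array. Genes were called where their replicates lay close together, so the steady values of called genes follow in part from this selection. Their calls were less steady than their values. Nr1d1 and Tnip3 kept their calls for Day 21 against Day 5 in all 16 alternatives. In that comparison Ccr2 kept its call in 8 of 16 and Ms4a4c in 4 of 15. At Day 21 against naive Lyve1 and Nr1d1 kept theirs in 10 of 16, Chil3 in 6 of 15 and Dgkh in 4 of 16. At Day 5 against naive Tnip3 and Treml4 kept theirs in 14 of 16, Siglec1 in 8 and Tfec in 3.

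The replicate numbers are shared between groups, but no label says that they pair samples, and the deviations of same-numbered arrays correlated at -0.014 (naive and Day 5), -0.25 (naive and Day 21) and 0.22 (Day 5 and Day 21). With the replicate block 44, 8 and 75 genes passed, of which 24, 4 and 68 were among the 53, 8 and 166, so that 4 of the 8 genes at Day 21 against naive lost their call. The overlap was 4, 22 calls of named genes were lost and 37 kept, and no list call changed. A crossed replicate block, chosen after seeing the data, gave 101, 0 (2094 at an unadjusted p under 0.05 in limma) and 317 genes, an overlap of 0, and 10 lists in each comparison, against 10, 10 and 11, the call lost being MHC class II for Day 21 against Day 5. Without a detection call, what dim signal limits cannot be said.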

Other observations

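The gene groups described here were chosen after the data were seen. All 7 measured CD209 lectin genes, which encode C-type lectins of myeloid cells, had positive changes at Day 5 against naive (mean 0.71, under each scaling), and all 7 had negative changes from Day 5 to Day 21 (mean -0.80). Cd209d passed the gene test in both comparisons, while Cd209f had changes of 1.38 ± 0.40 and -1.90 ± 0.40 that did not pass. The naive arrays spread widely in Cd209f (SD 1.02, n = 2), and binding of one member's probe sets to the transcripts of another was not tested. Of 7 Schlafen genes, which are interferon-responsive, 6 had negative changes at Day 5 under each scaling (mean -0.34), with Slfn4 past the test and Slfn5 at -0.57 ± 0.12. Each family was drawn up after Cd209d or Slfn4 was seen and includes it, so a test of either as a set would be void and none is given.

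In the clock list, Nr1d2, the partner of Nr1d1, fell from Day 5 to Day 21 (-1.30 ± 0.12), while Arntl, which both repress, had a change of -0.05 ± 0.08. Of 12 measured MS4A genes, Ms4a6b (-0.81 ± 0.08) and Ms4a4c fell from Day 5 to Day 21, while the family as a whole had a mean of -0.17 and a median of -0.014, with 6 members higher and 6 lower, or 5 and 7 with median centring or the values as deposited. Across genes, naive replicate 1 correlated with Day 21 replicate 2 at 0.99703 and with naive replicate 2 at 0.99653.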
